A study of Drosophila melanogaster with 48 samples.

How the data were processed

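The data are 48 Affymetrix Drosophila expression arrays, each hybridised with labelled RNA of adult Drosophila melanogaster, per the labels. Larvae of 8 numbered lines grew on 3 foods, which are standard cornmeal-molasses medium, the same medium with 9% ethanol, and the medium enriched with tomato paste. Each of the 24 combinations of line and food holds 2 arrays, so that each food has 16 arrays and each line has 6. The labels do not define the line numbers, which were taken as fly lines, and they give no sex. They give an age, 3 to 5 days, for 4 arrays. Nothing in the labels says that the 2 arrays of a combination came from separate cultures, so a p-value that rests on their spread measures only the difference between those arrays, which may be technical.

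The deposited values are signal intensities on a linear scale, made by the authors with MAS5, per the submitters' processing notes; no version is given there. Tested on the values, the mean signal of every array after trimming 2% at each end lay between 500.009 and 500.016, so that each array was scaled to a common target of 500. The median signal ran from 84.2 to 160.2. No detection calls, scan dates or scanner files were used here. No pair of arrays held identical values.

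The values were set to a floor of 1 and taken to log2 with no further normalisation between arrays. Of 18952 probe sets, 183 array controls were left out, and the 60% with the highest mean log2 signal over all 48 arrays were kept. That left 11261 probe sets above a mean signal of 59.7, with 4 single values at the floor. Of the 18769 probe sets other than controls, 13647 had 1 gene symbol in the platform table, 402 had several and 4720 had none listed; only the first kind are named. Gene numbers matched 13544 of them to the RefSeq gene table of assembly Release 6 plus ISO1 MT, which was used for names only, since no build is named for the probes. A gene with several tested probe sets is represented by the one with the highest mean signal, which gave 9419 genes.

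Media were compared with limma 3.58.1 in R 4.3.3 on the 24 means of the arrays of each combination, with line and medium as terms and an intensity trend in the variance prior. This leaves 14 residual degrees of freedom and sets the differences between media against their variation from line to line. Line differences averaged over media, and the line by medium interaction, were F-tests with 7 and 14 numerator degrees of freedom on the 48 arrays, with error from the spread within combinations and 24 residual degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Means in the text are mean log2 signals with the SD over the 8 lines, and a fold is 2 to the power of the log2 difference, whose size is uncertain for weak probe sets. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined.

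The rule named, for each contrast, the 10 largest rises and 10 largest falls among called genes that moved the same way in at least 7 of the 8 lines. Where under 5 genes passed, the 5 with the smallest p were named as not passing. For lines it named the 15 called genes with the largest range of line means, for the interaction the 15 smallest p, for each gene list up to 4 members with the smallest p, and in all cases Adh, Aldh, Orco, lush and Cyp6g1. Adh and Aldh had no tested probe set with a single symbol. There were 25 preset lists; 5 had under 3 tested genes and received no set test. For media the other 20 were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 60 tests. For lines and the interaction, Fisher's exact test compared the share of called members with that of all other tested genes. It treats genes as independent.

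The titles of 33 arrays set line, medium and array number apart with spaces; those of 15 run line and medium together and put a hyphen before the array number. The hyphen stands on 11 tomato, 4 ethanol and 0 standard arrays, and 5 tomato combinations hold 1 array of each kind. The spelling was treated as a possible batch. It was tested with limma within those 5 pairs, used as a block, and the comparisons were repeated in the arrays with a space alone. For media, the fits with a block or a covariate, and those in the arrays with a space, took single arrays. Their terms included line and medium, and their error is the spread of single arrays, not that of the 24 means. Counts and SEs from them thus differ from the main ones in more than the arrays used. An eggshell index, the mean log2 signal of 9 chorion and vitelline membrane genes of the female list, and cuticle, yolk protein, seminal fluid and testis indices, were computed for each array, with the difference between 3' and 5' probe sets of actin and GAPDH as a sign of RNA quality.

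Alternatives fixed in advance were quantile normalisation, centring on the median, no filter or the upper 40% of probe sets, a pseudocount at the 10th percentile of the deposited values (4.745), an adjusted p under 0.01, unmoderated statistics, leaving out each line, other error terms, 1 array per combination, blocks for array number and label style, and single media or pairs of media. Leaving out 9 arrays with an eggshell index more than 3 MADs under the median, and taking the eggshell index or principal component 1 as a covariate, were added after seeing the data.

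The models were tested on simulated data of 11261 probe sets with normal residuals of the real size and 67, 67 and 66 changed probe sets of rising size in each test, and 9 of 11061 unchanged probe sets were called for tomato versus standard. In that test, 65.7% of changes of 0.5 log2 units and 91.0% of changes of 1 unit were recovered. For line differences 74.6% of changes of 1 unit in 1 line were recovered, and for the interaction 10.4% of changes of 1 unit and 97.0% of changes of 4 units in 1 combination. The simulated residuals were independent between probe sets. Beyond the changes set, they held no line by medium variation and no title style difference. These rates therefore do not describe the real arrays, where another split of the media within lines called 1580 probe sets for tomato versus standard. The figures were drawn with matplotlib.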

Results

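Whole-body RNA profiles were compared among flies of 8 lines whose larvae had grown on standard cornmeal-molasses medium, on medium with 9% ethanol or on medium enriched with tomato paste. All adults lived on standard medium after eclosion, so the media comparisons ask what the larval food left in the adult transcriptome, and the line comparisons ask how far the lines differ and whether they respond alike. The submitters tied the profiles to behaviour toward benzaldehyde, an odorant; behaviour was not analysed here. There were 16 arrays per medium, 2 for each line, with 11261 probe sets tested. The correlation between the 2 arrays of a combination ranged from 0.783 to 0.991, with a median of 0.959, and from 0.945 to 0.991 on standard medium.

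Over all arrays, the metallothionein genes MtnD and MtnC were higher, and the eggshell genes yellow-g and Vm32E lower, on tomato medium than on standard medium. Hyphen titles stand on 11 tomato and 0 standard arrays, so these differences cannot be assigned to the medium alone. MtnD, which encodes a metal-binding metallothionein, had a mean log2 signal of 9.50 ± 1.54 on standard and 10.97 ± 1.33 on tomato medium (SD, n = 8 lines), a 2.77-fold difference. It was seen in 7 of 8 lines (SE 0.19 log2 units, adjusted p = 0.0051 with limma). MtnC, another metallothionein gene, rose 2.36-fold from 11.18 ± 0.63 to 12.42 ± 0.47 (SD, n = 8), in 8 of 8 lines (SE 0.18, adjusted p = 0.0051 with limma). Among falls, yellow-g, a gene of eggshell formation, went from 11.16 ± 0.55 to 8.65 ± 1.25 (SD, n = 8), a log2 difference of -2.51 (SE 0.58, adjusted p = 0.045 with limma). Vm32E, a vitelline membrane gene, had a log2 difference of -2.46 (SE 0.54), lower in 8 of 8 lines.

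Further genes that rose were LManIII, a lysosomal mannosidase (3.14-fold), hll (3.06-fold), CG13311 (2.68-fold), CG31091 (2.56-fold), CG3999 (2.26-fold), CG42807 (2.16-fold), CG34316 (2.10-fold) and CG11893 (2.07-fold). Further genes that fell had log2 differences of -2.07 for Obp19c, an odorant-binding protein gene, -1.64 for CG14834, -1.61 for CG43333 and -1.56 for psd, which encodes a vitelline membrane protein. Cad74A, a cadherin gene, fell by 1.11, CG17364 by 0.92, tj, a transcription factor of gonadal somatic cells, by 0.89 and Roe1, a mitochondrial cochaperone gene, by 0.87 on the log2 scale. In all, 129 probe sets were called, 92 higher and 37 lower, for 82 and 36 genes; 2383 had an unadjusted p under 0.05, where chance gives 563.05. The median size of a called difference was 0.59 log2 units.

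The calls did not hold among arrays of 1 title style. In the arrays titled with a space, which keep all 16 standard and 5 tomato arrays, 0 probe sets were called. There the median difference of the 129 in their called direction was 0.016 log2 units (quartiles -0.12 and 0.17), against 0.59 in all arrays. Of the 129, 69 kept their called direction there. There MtnD differed by 0.76 (SE 0.33) and MtnC by 0.62 (SE 0.23), while yellow-g differed by 0.32 (SE 0.80) and Vm32E by -0.11 (SE 0.50) log2 units. Opposite in sign there were also CG31091 (-0.26), CG42807 (-0.05), CG14834 (0.33), CG43333 (0.27) and Cad74A (0.31). With title style as a block 0 were called, with a median of 0.27 log2 units and 128 of the 129 in their called direction. That block fits 1 style difference for all media and can leave part of it in the tomato term. With array number as a block 0 were called. That block overlaps with title style, since no standard array carries a number found on the hyphen-titled tomato arrays. Without the 9 arrays of lowest eggshell index 0 were called too. Left out in turn, lines 158, 304, 362, 379, 380, 774, 786 and 859 gave counts of 10, 7, 31, 2856, 27, 2, 35 and 64.

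**Figure D1:**
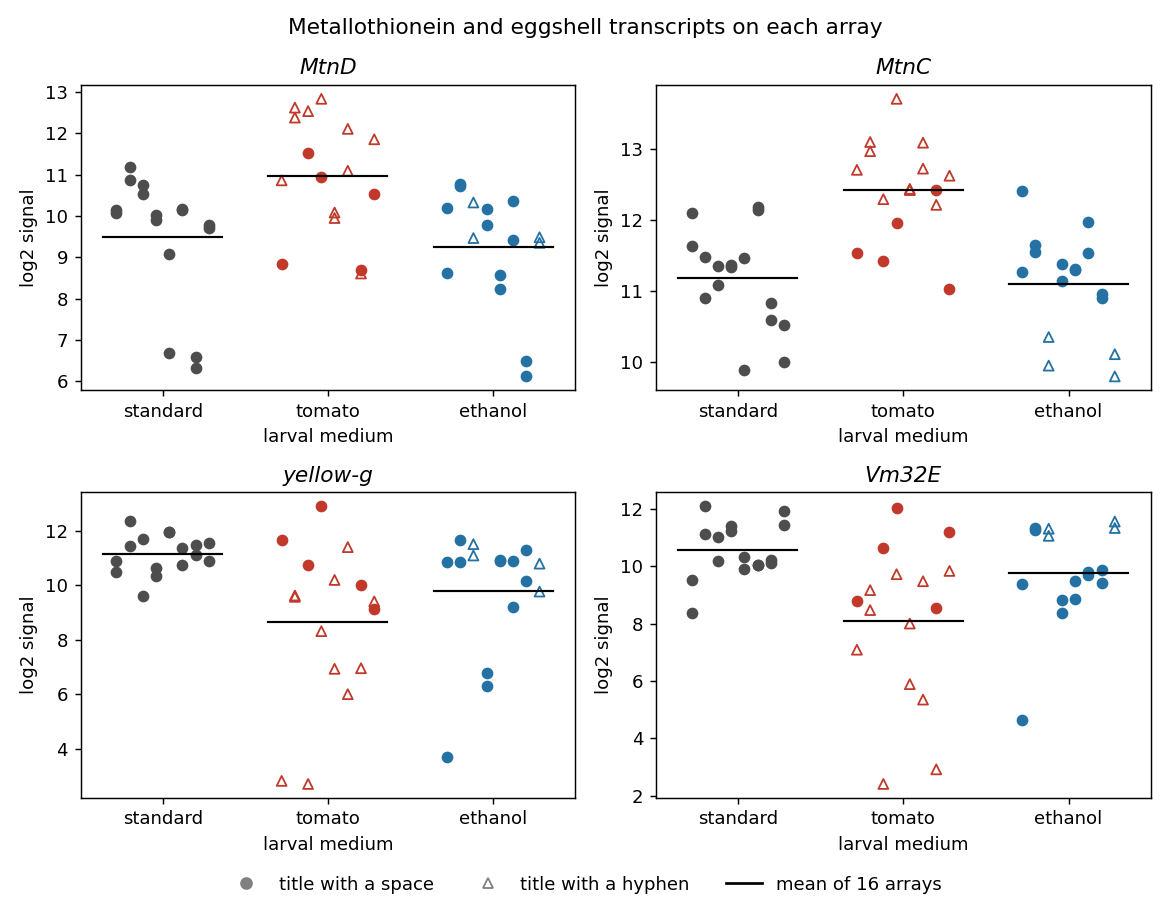
Log2 signal of MtnD, MtnC, yellow-g and Vm32E on each of the 48 arrays, by larval medium. Filled circles are arrays titled with a space, open triangles arrays titled with a hyphen, and bars the mean of 16 arrays.

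Of the 20 female reproductive genes tested, 19 had lower means on tomato medium and the median log2 difference was -1.46. One gene, Vm32E, fell past the threshold over all probe sets, and 16 did when adjusted over the list alone (camera adjusted p = 9.3e-07; adjusted p = 0.50 with an estimated correlation). In the arrays titled with a space the list median was 0.29, with 8 of 20 lower. Members that did not pass included Cp7Fc (-2.67, SE 0.73), a chorion gene, Vm26Ac (-1.79, SE 0.46) and Vm26Aa (-1.54, SE 0.46). The eggshell index was 13.21 ± 0.32 on standard, 11.27 ± 1.24 on tomato and 11.85 ± 2.15 on ethanol medium (SD, n = 8 lines). Its mean was 13.05 over the 5 tomato arrays titled with a space and 10.46 over the 11 titled with a hyphen. The 3' minus 5' difference of actin, a sign of RNA quality, was 2.14 ± 0.21 on standard, 1.86 ± 0.21 on tomato and 1.89 ± 0.19 on ethanol medium (SD, n = 8 lines). For the eggshell index, single arrays ran from 12.58 to 13.88 on standard medium, but down to 4.17 on tomato and 5.59 on ethanol medium.

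Of the detoxification genes 5 rose on tomato medium. Of 67 cytochrome P450 genes, 2 rose, Cyp6a21 by 0.68 (SE 0.14) and Cyp28d1 by 0.58 (SE 0.13) log2 units, and 65 did not pass. There were 7 that passed when adjusted over the list alone (camera adjusted p = 0.00035; adjusted p = 0.59 with an estimated correlation). Of 30 glutathione S-transferase genes 2 rose, GstE10 by 0.58 (SE 0.12) and GstD10 by 0.73 (SE 0.16), and 5 passed adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.50 with an estimated correlation). Of 23 UDP-glycosyltransferase genes 1 rose, Ugt302E1 by 0.91 (SE 0.21), and 5 passed adjusted over the list alone (camera adjusted p = 2.2e-05; adjusted p = 0.45 with an estimated correlation). In the arrays titled with a space, Cyp28d1 differed by -0.24, Cyp6a21 by -0.03, Ugt302E1 by -0.19, GstE10 by 0.10 (SE 0.21) and GstD10 by 0.14 (SE 0.26), none of them passing. Over all arrays within lines, 57 of 67 P450 genes ran against the eggshell index (median r = -0.44), as did 23 of 30 glutathione S-transferase (-0.30) and 21 of 23 UDP-glycosyltransferase genes (-0.46), and that index had a lower mean on tomato medium.

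The clock gene tim, whose protein is part of the circadian feedback loop, rose by 0.82 log2 units (SE 0.14, adjusted p = 0.015 with limma) in 8 of 8 lines. It was the only one of 8 clock genes past the threshold, and 3 passed adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.50 with an estimated correlation). In the arrays titled with a space tim differed by -0.15 (SE 0.18). Of 34 digestive enzyme genes 1 rose, Mal-A2, a maltase gene, by 0.68 (SE 0.16), against -0.21 (SE 0.21) in the arrays titled with a space. In this list 16 passed adjusted over the list alone and the list as a whole did not shift (camera adjusted p = 0.46; adjusted p = 0.83 with an estimated correlation). Of 30 odorant-binding protein genes Obp49a rose by 0.59 (SE 0.12) and Obp19c fell, but in the arrays titled with a space they differed by -0.35 (SE 0.18) and 0.42 (SE 0.63). Here 3 passed adjusted over the list alone, and the list did not shift (camera adjusted p = 0.17; adjusted p = 0.83 with an estimated correlation). Of 26 accessory gland genes 1, Sfp26Ad, fell by 0.46 (SE 0.10; a difference of -0.10, SE 0.13, in the arrays titled with a space), and 22 had lower means (camera adjusted p = 0.00036; adjusted p = 0.65 with an estimated correlation).

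None of the 41 ribosomal protein genes passed, though 36 had lower means, with a median of -0.12 (camera adjusted p = 0.00059; adjusted p = 0.70 with an estimated correlation). None of 11 neuronal genes passed, with 10 higher means and a median of 0.31 (camera adjusted p = 0.0023; adjusted p = 0.63 with an estimated correlation), nor did any of 13 feeding and insulin genes, with 10 higher means (camera adjusted p = 0.012; adjusted p = 0.50 with an estimated correlation). Within lines, 11 of 11 neuronal (median r = -0.70) and 12 of 13 feeding and insulin genes (-0.45) ran against the eggshell index. That index had a lower mean on tomato medium. The ribosomal genes ran against it too, in 36 of 41 cases (-0.16), yet had lower means. None of 33 cuticle, 18 testis, 17 muscle, 13 phototransduction, 9 antimicrobial, 9 hemocyte, 8 heat shock, 6 peptidoglycan recognition or 5 ethanol metabolism genes passed, and none of these lists was called. The receptors of smell and taste were hardly measured in whole flies: 1 of 57 odorant receptor, 0 of 56 gustatory and 0 of 53 ionotropic receptor genes passed the signal filter, as did 1 of 5 Turandot and 1 of 3 larval serum protein genes. The odorant coreceptor gene Orco had log2 signals of 6.47 ± 0.22 on standard and 6.57 ± 0.45 on tomato medium (SD, n = 8), and lush, an odorant-binding protein gene, 7.51 ± 0.27 and 7.65 ± 0.45. Cyp6g1, a P450 gene known for insecticide resistance, was at 14.22 ± 0.18 and 14.20 ± 0.16.

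On ethanol medium no single gene passed the threshold against standard medium. The smallest p values belonged to NimC3, a Nimrod-family receptor gene, which was 1.45-fold higher (5.96 ± 0.40 against 6.50 ± 0.37, SD, n = 8 lines), puc, a phosphatase gene of the JNK pathway, 1.29-fold higher, and Jon25Biii, a digestive protease gene, with a log2 difference of -0.52 (SE 0.10). CG17364 had a log2 difference of -0.63 (SE 0.13) and Ythdc1, a gene of an RNA methylation reader, of -0.35 (SE 0.08). All 5 went the same way in 8 of 8 lines, with limma adjusted p values from 0.49 to 0.73. Genes of ethanol metabolism did not pass, with Fdh at -0.15 (SE 0.08), Men at -0.14 (SE 0.09), AcCoAS at -0.13 (SE 0.09) and Gpdh1 at 0.08 (SE 0.15) log2 units. The list of 5 was not called (camera adjusted p = 0.14, or 0.59 with an estimated correlation). Adh and Aldh were not among the 5, as they had no tested probe set with a single symbol.

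As groups, digestive enzyme genes had lower means on ethanol medium in 29 of 34 cases, with a median of -0.12, and 3 passed when adjusted over the list alone (camera adjusted p = 3.0e-06; adjusted p = 0.42 with an estimated correlation). Examples were Jon25Bi at -0.34 (SE 0.09), Jon65Ai at -0.51 (SE 0.15) and Jon99Ci at -0.31 (SE 0.11). Of 9 antimicrobial peptide genes 8 had lower means, among them Def, which encodes defensin, at -1.02 (SE 0.31), and 1 passed adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.50 with an estimated correlation). Ribosomal protein genes had lower means in 35 of 41 cases (median -0.10; camera adjusted p = 1.0e-06; adjusted p = 0.59 with an estimated correlation), and female reproductive genes in 18 of 20, with Cp15 at -1.67 (SE 0.60) and Cp36 at -1.59 (SE 0.77) (camera adjusted p = 8.9e-06; adjusted p = 0.59 with an estimated correlation). The eggshell index lay at 5.59 on 1 ethanol array of line 158 and at 6.88 and 8.40 on those of line 379, against 12.34 to 13.65 on the other 13. Without line 379 its difference from standard medium went from -1.36 to -0.82. All 11 neuronal genes had higher means, Rdl by 0.40 (SE 0.17), and none passed (camera adjusted p = 0.0082; adjusted p = 0.65 with an estimated correlation). Within lines these 11 genes ran against the eggshell index (median r = -0.70), which was low on those 3 ethanol arrays. UDP-glycosyltransferase genes had higher means in 18 of 23 cases (camera adjusted p = 0.014; adjusted p = 0.63 with an estimated correlation), and accessory gland genes lower means in 18 of 26 (camera adjusted p = 0.029; adjusted p = 0.81 with an estimated correlation). The other lists were not called.

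In all, limma called 0 probe sets at the adjusted threshold, and unmoderated statistics 0; 628 had an unadjusted p under 0.05 against 563.05 by chance. In the arrays titled with a space, 40 were called, 13 higher and 27 lower, and with title style as a block 13. Both fits took single arrays instead of the 24 means, so their error differs from that of the main test. With error between arrays of a combination, 9 were called over all arrays. The arrays titled with a space hold no ethanol array of lines 362 and 859. They keep the 3 ethanol arrays with a low eggshell index.

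MtnD and MtnC were also higher on tomato than on ethanol medium. MtnD was 3.28-fold higher (10.97 ± 1.33 against 9.25 ± 1.37, SD, n = 8 lines; adjusted p = 0.00087 with limma) and MtnC 2.49-fold (12.42 ± 0.47 against 11.10 ± 0.71, SD, n = 8; adjusted p = 0.0040 with limma), each in 8 of 8 lines. The secreted serine protease genes Ser8 (2.29-fold), Phae1 (1.63-fold) and Jon99Ci (1.51-fold) were higher on tomato medium, as were Listericin, an immune-induced gene (1.98-fold), Miox, an inositol oxygenase gene (1.87-fold), CG14963 (1.84-fold), CG16727 (1.67-fold) and CG11899 (1.44-fold). In all, 12 probe sets were called, 12 higher and 0 lower; 757 had an unadjusted p under 0.05. With title style as a block the count was 2, at log2 differences of 1.51 (SE 0.24) for MtnD and 1.22 (SE 0.20) for MtnC. With array number as a block the count was 0, so neither gene passed (smallest adjusted p = 0.26 with limma). The arrays titled with a space gave 16, 2 higher and 14 lower, with MtnD at 0.90 (SE 0.36) and MtnC at 0.52 (SE 0.25), neither passing. There Ser8 (-0.12, SE 0.29), CG14963 (-0.35, SE 0.15) and CG16727 (-0.27, SE 0.19) were opposite in sign, and Phae1 (0.20), Jon99Ci (0.19), Listericin (0.09), Miox (0.24) and CG11899 (0.17) were smaller. The count was 0 without the 9 arrays of lowest eggshell index, and 2, 3, 5, 376, 3, 2, 5 and 8 without lines 158, 304, 362, 379, 380, 774, 786 and 859.

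Digestive enzyme genes had higher means on tomato than on ethanol medium in 22 of 34 cases, with a median of 0.25. Jon99Ci passed over all probe sets and 10 passed adjusted over the list alone (camera adjusted p = 1.0e-07; adjusted p = 0.39 with an estimated correlation). Mal-B2, a maltase gene, stood at 0.60 (SE 0.13) and Mal-A6 at 0.59 (SE 0.15). All 9 antimicrobial peptide genes had higher means, Drsl3 by 1.77 (SE 0.50) and Def by 1.03 (SE 0.31) log2 units, and 2 passed adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.42 with an estimated correlation). Of 30 glutathione S-transferase genes 24 had higher means, with GstD10 at 0.56 (SE 0.16) and GstD2 at 0.49 (SE 0.15), and 3 passed adjusted over the list alone (camera adjusted p = 4.9e-05; adjusted p = 0.39 with an estimated correlation). All 5 ethanol metabolism genes had higher means, with AcCoAS, an acetyl-CoA synthetase gene, at 0.38 (SE 0.09), and 1 passed adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.42 with an estimated correlation).

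Further lists were called between tomato and ethanol medium at the preset correlation alone, with no member past the threshold over all probe sets. UDP-glycosyltransferase genes had higher means in 18 of 23 cases, Ugt304A1 by 0.39 (SE 0.11), and 3 passed adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.50 with an estimated correlation). Cytochrome P450 genes had higher means in 43 of 67 cases, Cyp9b2 by 0.30 (SE 0.09) (camera adjusted p = 0.00016; adjusted p = 0.59 with an estimated correlation), and odorant-binding protein genes in 18 of 30, Obp49a by 0.52 (SE 0.12) (camera adjusted p = 0.0092; adjusted p = 0.69 with an estimated correlation). Feeding and insulin genes were higher in 11 of 13 cases, tobi by 0.59 (SE 0.22) (camera adjusted p = 0.0018; adjusted p = 0.45 with an estimated correlation). Clock genes were higher in 6 of 8, tim by 0.49 (SE 0.14) (camera adjusted p = 0.0036; adjusted p = 0.45 with an estimated correlation), and muscle genes in 17 of 17 (camera adjusted p = 0.025; adjusted p = 0.81 with an estimated correlation). Within lines, 17 of 17 muscle genes (median r = -0.48) and 7 of 8 clock genes (-0.51) ran against the eggshell index. Of the arrays with a low index, 6 were tomato and 3 ethanol arrays. Female reproductive genes had lower means in 18 of 20 cases, vas by 0.48 (SE 0.16) (camera adjusted p = 0.0028; adjusted p = 0.69 with an estimated correlation), and accessory gland genes in 21 of 26 (camera adjusted p = 0.0031; adjusted p = 0.71 with an estimated correlation). The other lists were not called. Over the 3 contrasts the preset correlation gave 28 list calls in 60 tests, 9 for tomato, 7 for ethanol and 12 between these, and the estimated correlation gave 0.

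Asked whether any of the 3 media differed, limma called 34 probe sets for 30 genes, with MtnD at an adjusted p of 0.0014 and MtnC at 0.0040. The tomato and ethanol differences from standard medium correlated over the probe sets at r = 0.788, with 79.9% of signs shared and a covariance of 0.042. Both contrasts use the same standard arrays. Simulated unchanged groups gave a mean r of 0.49 and a mean covariance of 0.014, and 28 of 100 such draws had a correlation as high. With the standard arrays split between the contrasts, r was 0.614 or 0.628, reached by 12 of 100 draws for either split. Probe sets are not independent replicates. With the standard arrays split, single draws of unchanged groups ran from r = -0.95 to r = 0.80. So wide a spread cannot show whether tomato and ethanol medium share an effect, and no conclusion is drawn from it.

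Arrays with different title styles differed widely within the same line and medium. In the 5 tomato pairs with 1 array of each kind, yellow-g was lower in the hyphen-titled array, with a log2 difference of -4.84, as were the chorion gene Cp16 (-4.08), Vm32E (-3.84) and the oocyte gene osk (-0.67). Higher were tim (1.54 at its brighter probe set), MtnD (1.24), MtnC (1.03) and Cht5, a chitinase gene (1.79) (limma, each adjusted p under the threshold, n = 5 pairs). The yolk protein gene Yp1 differed by -0.19 (limma adjusted p = 0.34). Of 11261 probe sets, 4856 were called, 2014 higher and 2842 lower in the hyphen-titled arrays. The eggshell index was lower in the hyphen-titled array of 5 of 5 pairs, with 4.17 against 12.98 in line 362 and 11.40 against 12.93 in line 859.

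**Figure D2:**
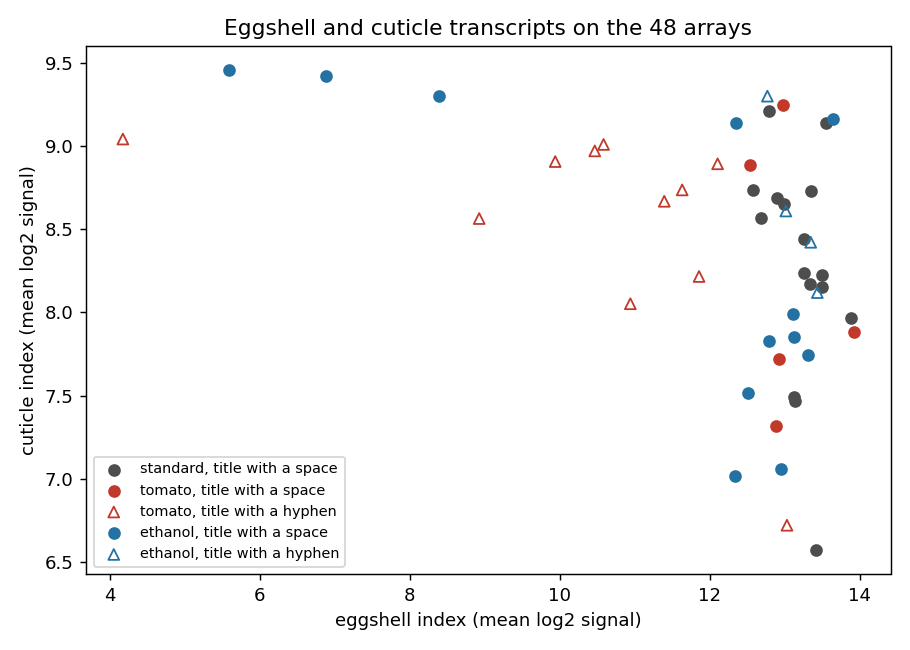
Eggshell index, the mean log2 signal of 9 chorion and vitelline membrane genes, against the cuticle index, the mean of 33 cuticle protein genes, on each of the 48 arrays; colours give the larval medium, and open triangles mark arrays titled with a hyphen. Standard arrays lie between 12.58 and 13.88 on the eggshell axis, and the arrays further to the left are tomato or ethanol arrays.

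Lines differed far more than media. Obp51a, an odorant-binding protein gene, had line means from 2.48 in line 859 to 11.49 in line 786, over 6 arrays per line. Jon74E, a digestive protease gene, fell into separate levels, near 6.83 to 7.05 in lines 304, 362 and 786 and 13.54 to 13.93 in the other lines, a 137-fold range. Single lines stood far below the rest for several genes. MtnB, a metallothionein gene, was at 2.29 in line 362 against 7.16 to 9.86 elsewhere. NaPi-III, a phosphate transporter gene, was at 3.92 in line 304 against 10.39 to 11.12. Acbp3, an acyl-CoA binding protein gene, was at 4.93 in line 380 against 10.92 to 12.43, and CG5614 at 2.81 in line 379 against 9.21 to 9.96.

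The other genes with the largest ranges, with their lowest and highest line means, were Cyp12d1-d (2.61 and 11.05), whose near-identical neighbour Cyp12d1-p makes its probe signal uncertain, CG30083 (1.81 and 9.61), Pepck2, a phosphoenolpyruvate carboxykinase gene (2.32 and 10.06), lncRNA:CR33942 (1.99 and 9.58) and CG9259 (4.12 and 11.36). They also included wa-cup (1.43 and 8.57), CG8343 (4.48 and 11.59), CG3397 (1.31 and 8.41) and CG4757 (3.40 and 10.46). These low line means, and those of Obp51a, MtnB, NaPi-III, Acbp3 and CG5614, lie under the filter's signal of 59.7 and are not shown to be above background, so the exact size and order of these ranges are not known. Line differences were called for 6954 probe sets (61.8% of those tested), for 5841 genes, with a median range of 0.89 log2 units. There were 98 genes with a measured range of at least 16-fold, of which 59 had 1 line below all others by at least 2 log2 units, against 3 with 1 line above. The filter on the mean signal over all arrays keeps genes low in 1 line more readily than genes high in 1 line. The counts of 59 and 3 therefore do not show which kind is commoner. The F-tests used error between arrays of a combination. Tested on standard medium alone, 5468 probe sets were called, against 540 on tomato and 2001 on ethanol medium. The correlation between the 2 arrays of a combination was at least 0.945 on standard medium. It went down to 0.840 on tomato and 0.783 on ethanol medium. Fewer calls there can come from this wider error and do not show that lines differed less.

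**Figure D3:**
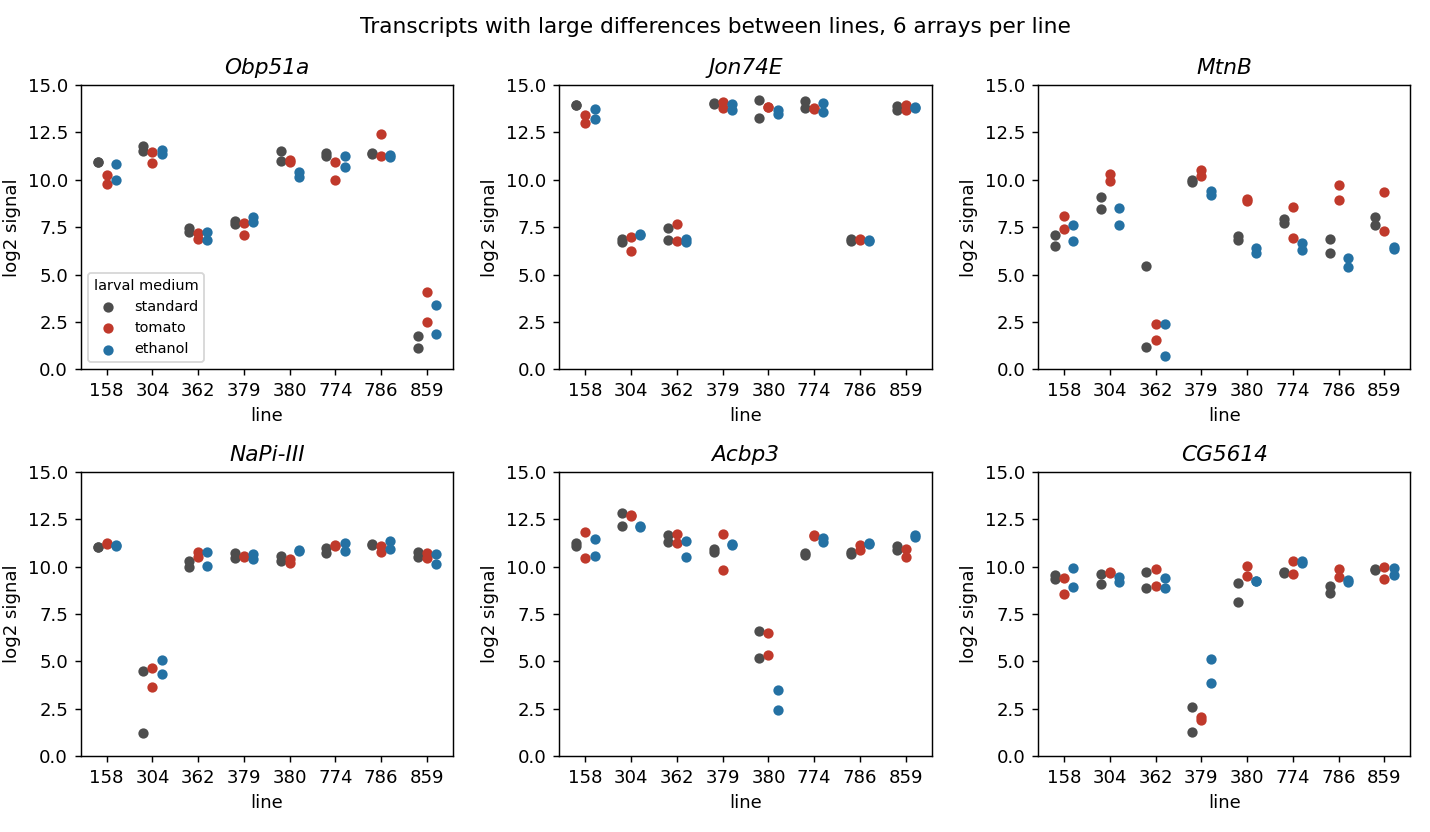
Log2 signal of Obp51a, Jon74E, MtnB, NaPi-III, Acbp3 and CG5614 on each of the 6 arrays of the 8 lines, with colours for the larval medium. The points show the low line means of 2.48 for Obp51a in line 859, 2.29 for MtnB in line 362, 3.92 for NaPi-III in line 304, 4.93 for Acbp3 in line 380 and 2.81 for CG5614 in line 379.

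Detoxification, seminal fluid and digestive genes were called between lines in larger shares than other genes over all arrays. Fisher's exact test treats genes as independent, and neither correlation between list members nor signal level was allowed for. Between media, an estimated correlation took the list calls from 28 to 0. The adjusted p values for lines may therefore be too small. Sequence differences between lines under the probes can also give a line call. Whether they do so more often in some lists was not tested, so a larger share is not shown to be one of RNA levels. Of 67 cytochrome P450 genes 58 were called, and 59 adjusted over the list alone, against 61.8% of the other genes (Fisher's exact test, adjusted p = 7.9e-05). Cyp6a17 was at 4.88 in line 304 and 10.85 in line 786, Cyp6a18 at 2.35 in line 380 and 9.04 in line 786. Of 23 UDP-glycosyltransferase genes 21 were called (22 adjusted over the list alone; exact adjusted p = 0.0094), with a 23.8-fold range for Ugt35C1, and of 30 glutathione S-transferase genes 25 (26 adjusted over the list alone; exact adjusted p = 0.041), with ranges of 10.8-fold for GstE1 and 10.7-fold for GstE13. Of 26 accessory gland genes 24 were called (24 adjusted over the list alone; exact adjusted p = 0.0042), among them Acp98AB with an 11.5-fold range. Of 34 digestive enzyme genes 28 were called (28 adjusted over the list alone; exact adjusted p = 0.041), Jon99Ci at 6.06 in line 786 and 12.62 in line 304, and Jon65Aii with a 35.4-fold range.

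Female reproductive and ribosomal protein genes were called in smaller shares, 2 of 20 (2 adjusted over the list alone; exact adjusted p = 2.1e-05) and 10 of 41 (7 adjusted over the list alone; exact adjusted p = 2.1e-05). The called female genes were vas and grk, both of the germ line. The limits given above, of the exact test and of the probes, hold for these lists too. Without the 9 arrays of lowest eggshell index, in a fit with no interaction term, the P450 (exact adjusted p = 0.0049), digestive (0.044), female (0.044) and ribosomal (1.5e-07) lists stayed called. The called share of the female list was 35% there, against 10% over all arrays, and that of the ribosomal list 19.5% against 24.4%. The glutathione S-transferase (0.11), UDP-glycosyltransferase (0.23) and accessory gland (0.49) lists did not, and the odorant-binding protein list was called (0.044). The median range of line means was 1.81 log2 units over the female list, most of which did not pass, and 0.27 over the ribosomal list. Odorant-binding protein genes were called in 24 of 30 cases, with a 5.19-fold range for Obp57a. Testis genes were called in 15 of 18, with a 15.4-fold range for dj, and antimicrobial genes in 7 of 9, with a 25.0-fold range for Drsl4. Clock genes were called in 6 of 8, with a 7.39-fold range for Clk, and ethanol metabolism genes in 4 of 5. These shares were not shown to differ from the 62.0% of other genes (exact adjusted p from 0.14 to 0.82), but lists this small cannot show equal shares. The same held for 17 of 33 cuticle, 13 of 17 muscle, 10 of 13 feeding and insulin, 9 of 13 phototransduction, 7 of 9 hemocyte, 6 of 11 neuronal, 5 of 8 heat shock and 5 of 6 peptidoglycan recognition genes. Cyp6g1 differed 1.36-fold between lines (limma adjusted p = 0.011), while lush (1.83-fold) and Orco (1.78-fold) did not pass.

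No gene passed the test of whether the effect of the media differed between lines. The smallest p values were those of Rpt3R, a proteasome subunit gene (F = 7.01), Psf1, a DNA replication gene (F = 6.43), CG32712 (F = 6.34), CG15649 (F = 6.29) and geko (F = 6.18), each with a limma adjusted p of 0.057. They were followed by CG13026, CG18180, TTLL1B, Mst27D, CG7203, CG17821, blanks, Gli, Mur29B and CG33252, with adjusted p values from 0.063 to 0.14. None of the 20 lists had a called member; adjusted over the list alone, 3 hemocyte, 2 antimicrobial, 2 heat shock, 2 cuticle and 1 glutathione S-transferase genes passed, and 0 in the other lists. At the adjusted threshold limma called 0 probe sets and unmoderated F-tests 4; 1453 had an unadjusted p under 0.05, against 563.05 by chance. With title style as a term 1834 were called, and without the 9 arrays of lowest eggshell index 316; in the arrays titled with a space 0 were called.

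The variance of a probe set was divided among line, medium, their interaction and the arrays of a combination. The median share was 20.4% for line (quartiles 8.53% and 39.2%), 0.80% for medium (quartiles 0 and 5.96%), 7.62% for the interaction and 60.2% for the difference between arrays of a combination. Principal component 1 held 38.9% of the variance of the tested probe sets. The 11 female genes outside the eggshell index followed it from array to array within lines, with a median r of 0.84 and 10 of 11 positive, and the 11 neuronal genes ran against it, with a median r of -0.70 and 11 of 11 negative.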

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

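The comparisons by label style were planned, but the limits they were held to here, and the tests of the low eggshell arrays, of other splits of the arrays and of females, RNA quality and age were chosen after the result was seen; those of probe pairs were not, except the rule that under 6 genes decide nothing. Dixon's rule, which compares the gap of the most distant value with the whole range, flags about 1 in 20 groups by chance. Here it flagged 20 of 58 groups, a share that cannot be set against that rate, since 10 of the 20 are line means of genes picked for their large range.

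Line 158 stood apart for the metallothioneins. Its MtnD difference between tomato and standard medium was -0.26 log2 units, against 1.39 to 2.20 in the other lines (gap over range 0.671). Between tomato and ethanol medium line 158 had 0.45 for MtnD against 1.62 to 2.35 (0.616), and 0.28 for MtnC against 1.13 to 1.88 (0.531). For tj, line 859 differed by -0.36 between tomato and standard medium, against -1.13 to -0.89 (0.684).

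Single lines stood far below the others for 10 of the 15 genes with the largest line ranges. The filter on mean signal favours such genes over genes high in 1 line. Line 304 did so for Pepck2 (2.32 against 6.72 to 10.06; gap over range 0.5682), NaPi-III (3.92 against 10.39 to 11.12; 0.899), wa-cup (1.43 against 7.92 to 8.57; 0.909) and CG8343 (4.48 against 11.15 to 11.59; 0.939). Line 380 did for Acbp3 (4.93 against 10.92 to 12.43; 0.799) and CG9259 (4.12 against 9.62 to 11.36; 0.760). Line 158 did for lncRNA:CR33942 (1.99 against 8.66 to 9.58; 0.879), line 362 for MtnB (2.29 against 7.16 to 9.86; 0.643), line 379 for CG5614 (2.81 against 9.21 to 9.96; 0.895) and line 859 for CG3397 (1.31 against 7.71 to 8.41; 0.901).

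One array of 6 stood apart in the eggshell index of 6 lines. These were an ethanol array of line 158 (5.59 against 10.47 to 13.11; gap over range 0.649) and tomato arrays of lines 362 (4.17 against 12.77 to 13.44; 0.928), 380 (8.93 against 11.86 to 13.50; 0.642), 774 (9.94 against 12.36 to 13.50; 0.679), 786 (10.59 against 12.54 to 13.14; 0.767) and 859 (11.40 against 12.93 to 13.35; 0.784).

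The 129 probe sets called between tomato and standard medium, with MtnC and MtnD up and yellow-g and Vm32E down, are the first pattern. A difference between label styles cannot be told apart from one between media. In arrays titled with a space, which keep only 5 tomato arrays, the median difference kept 2.68% of its size. There 69 of 129 kept the called direction. With title style as a block it kept 46.4%, with 128 of 129 in the called direction. That block fits 1 style difference for all media. The eggshell index, though, was lower in hyphen-titled tomato arrays (10.46 against 13.05) and higher in hyphen-titled ethanol arrays (13.14 against 11.42). The block can therefore leave part of the style difference in the tomato term. The 129 were called from these same arrays, so their direction is not independent support. In the 5 mixed pairs, the hyphen-titled arrays lay further in the called direction in 129 of 129. The median was 1.00 log2 units, and these arrays entered the calls. The low eggshell arrays stay open as a source too, since 50.7% of the median difference stayed without these 9; of them the 6 tomato arrays have hyphen titles and the 3 ethanol arrays titles with a space, while the 4 hyphen-titled ethanol arrays had indices of 12.77 to 13.44. Chance division of the arrays was argued against, as 2 of 100 splits of the media within lines, the real one included, called as many, although another split called 1580, which points to structure of the samples beyond the media. An effect of tomato medium on MtnC and MtnD stays open, with differences of 0.62 (SE 0.23) and 0.76 (SE 0.33) in the arrays titled with a space.

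Eggshell transcripts, which vary between arrays of a line, are the second pattern. Fewer females in some pools are argued against as the whole source. The oocyte genes osk, bcd and grk had slopes of 0.18 (SE 0.01), 0.52 (SE 0.03) and -0.05 (SE 0.01) on the eggshell index. Their median was 0.178, where loss of females needs about 1. A smaller part is not excluded. Of the male markers the testis index rose where the eggshell index fell (r = -0.58, permutation adjusted p = 0.00012). The seminal fluid index did not (r = -0.05, permutation adjusted p = 0.74). The rise was not particular to male genes. Within lines, 11 of 11 neuronal (median r = -0.70) and 17 of 17 muscle genes (-0.48) also ran against the index, while heat shock genes did not (0.08). The testis index therefore does not decide on a share of males. The yolk protein slope of 0.11 (SE 0.02) was looked at first and set aside because yolk signals lie near the top of the scale. Degraded RNA is argued against, since the 3' minus 5' actin difference rose with the eggshell index (r = 0.333; 0.27, 0.20 and 0.16 on standard, tomato and ethanol medium, 0.33 and -0.01 in arrays titled with a space and a hyphen) instead of falling. Younger flies cannot be excluded or shown, with r = -0.478 between cuticle and eggshell index (permutation adjusted p = 0.0010, rho = -0.51, r = -0.53 without the 2 farthest arrays; 0.16, -0.48 and -0.64 on standard, tomato and ethanol medium, and -0.48 and -0.40 in arrays titled with a space and a hyphen). A change of late oogenesis by larval food stays open and was not tested.

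Measured line ranges of at least 16-fold are the third pattern, seen in 98 genes. Sequence differences under the probes cannot be told apart from differences in RNA: 94 of these genes have 1 tested probe set, and for the other 4 the median r of line means between probe sets was -0.062, from -0.90 to 0.83, too few to decide. Among 115 genes with a range of at least 1 log2 unit and a further probe set, the median r was 0.65. Differences between the genotypes in transcript level stay open.

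The other counts were set against splits of the arrays as well. For ethanol versus standard medium and for the interaction the real count is 0, so that 100 of 100 splits call as many by construction and decide nothing. As many probe sets as in the real groups were called in 2 of 100 for tomato versus ethanol medium, 2 of 100 for any medium and 1 of 100 for lines, always with the real one included. The highest other counts were 3780 for tomato versus ethanol medium, 1993 for any medium and 1228 for the interaction, which again points to structure of the samples, and 32 for lines.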

How the results depend on the processing

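The settings without the 9 arrays of low eggshell index and with the eggshell index or principal component 1 as covariate were chosen after the result was seen. The cause of a change was not tested unless stated. Line differences kept within 1.5 times of 6954 under all settings on all media (4684 to 9100). They fell to 540 on tomato and 2001 on ethanol medium alone, against 5468 on standard medium alone with as many arrays. Some pairs of arrays of a combination lay further apart on tomato and ethanol medium. These counts therefore do not show smaller line differences there.

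For tomato versus standard medium (129), quantile normalisation gave 209, no filter 73, an adjusted p under 0.01 7, error between arrays of a combination 884, the lower-numbered arrays 0 and the higher-numbered 2318, title style as a block 0, arrays titled with a space 0, leaving out the 9 arrays 0, and the eggshell and principal component covariates 25 and 1571. Every hyphen-titled tomato array is numbered 3 or 4, and every space-titled one 1 or 2. The higher-numbered tomato arrays are thus all hyphen-titled. Settings by array number, the replicate block included, therefore overlap with those by title style. Leaving out lines gave 2 to 2856: 10 without line 158, 7 without 304, 31 without 362, 2856 without 379, 27 without 380, 2 without 774, 35 without 786 and 64 without 859.

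For ethanol versus standard medium (0), error between arrays of a combination gave 9, title style as a block 13, arrays titled with a space 40, and the covariates 6 and 374. For tomato versus ethanol medium (12), an adjusted p under 0.01 gave 3, unmoderated statistics 4, error between arrays of a combination 21, the lower-numbered arrays 0 and the higher-numbered 603, title style as a block 2, leaving out the 9 arrays 0, and the covariates 38 and 170. Leaving out lines gave 2, 3, 5, 376, 3, 2 and 5 without lines 158, 304, 362, 379, 380, 774 and 786.

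For any medium difference (34), no filter gave 17, an adjusted p under 0.01 3, unmoderated statistics 12, error between arrays of a combination 269, the lower-numbered arrays 0 and the higher-numbered 1250, title style as a block 4, leaving out the 9 arrays 0, and the covariates 64 and 1407. Leaving out lines gave 2, 3, 6, 1561, 3, 2, 9 and 22 in the order of their numbers.

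For the interaction (0), quantile normalisation gave 11, centring on the median 4, unmoderated statistics 4, leaving out lines 158, 304 and 774 gave 21, 5 and 6, leaving out standard medium 3 and tomato medium 1, title style as a term 1834, leaving out the 9 arrays 316 and the principal component covariate 20. List calls between media (28) went to 0 with an estimated correlation, list calls between lines (7) to 12 with no filter and 5 without the 9 arrays, and label style calls (4856) to 3220 without line 158 and 3038 without line 859, with 4811 the highest left-out count.

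With array number as a replicate block the counts were 0 for tomato versus standard, 8 for ethanol versus standard, 0 for tomato versus ethanol and 0 for any medium. Reversed there between tomato and standard medium were CG31091 (-0.0750), Obp49a (-0.16), Cyp28d1 (-0.0862), Ugt302E1 (-0.18) and Mal-A2 (-0.0585), and between tomato and ethanol medium CG14963 (-0.0492). In the check of pairing, the correlation of differences between equal numbers was over 0.1 in 3 of 7 lines (-0.56 to 0.63), so numbers were not used to pair arrays.

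In arrays titled with a space, these were reversed between tomato and standard medium: CG31091 (-0.26), CG42807 (-0.0480), yellow-g (0.32), Obp19c (0.42), CG14834 (0.33), CG43333 (0.27), Cad74A (0.31), Obp49a (-0.35), Cyp6a21 (-0.0296), Cyp28d1 (-0.24), Ugt302E1 (-0.19), Mal-A2 (-0.21) and tim (-0.15). Between tomato and ethanol medium Ser8 (-0.12), CG14963 (-0.35) and CG16727 (-0.27) were. Of the other values for named genes between tomato and standard medium 1023 were the same, 337 weaker and 97 stronger. Between tomato and ethanol medium these counts were 508, 105 and 21. Weaker means passing in the main fit but not in the setting. Values that passed in neither were counted as the same, so these totals do not show that the calls were stable. In the lower-numbered arrays, where 0 probe sets were called, 29 of 65 values were weaker for tomato versus standard medium. For tomato versus ethanol medium 10 of 28 were. The filter at a signal of 59.7 limits what weak transcripts, such as receptor genes, can show.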

Other observations

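The values in this part were chosen after the result was seen. The other metallothionein genes did not pass between media. MtnB differed by 1.71 log2 units between tomato and ethanol medium (SE 0.34, limma adjusted p = 0.058), higher in 8 of 8 lines, and by 0.83 between tomato and standard medium (adjusted p = 0.18). MtnA differed by 0.32 (adjusted p = 0.27) and 0.25 (adjusted p = 0.14).

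Within lines, female genes outside the eggshell index followed it with unequal slopes, at 1.24 for Cp7Fc, 0.68 for Vm26Ac, 0.52 for bcd, 0.45 for otu, 0.18 for osk and -0.05 for grk; the mean slope of index members is 1 by construction. Against the index ran 13 of 13 phototransduction genes (median r = -0.58), 17 of 17 muscle genes (median r = -0.48) and 18 of 18 testis genes (median r = -0.51). The yolk protein index followed it (r = 0.63, rho = 0.50, permutation adjusted p = 0.00012, r = 0.41 without the 2 farthest arrays; 0.40 and 0.80 in arrays titled with a space and a hyphen). Of the 59 genes low in 1 line, 13 were low in line 362, 12 in line 304 and 11 in line 380.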
